A study of Bacillus subtilis PY79 and Staphylococcus aureus with 104 samples.

How the data were processed

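The series holds 104 libraries from Bacillus subtilis strains derived from PY79 and Staphylococcus aureus strains derived from HG003. Per the labels' protocols, B. subtilis was grown in a rich casein hydrolysate medium (CH) at 37 °C, S. aureus in tryptic soy broth, and cells for Hi-C and ChIP were fixed with 3% formaldehyde for 30 min. There were 33 Hi-C libraries, 19 anti-SMC, 11 anti-GFP, 2 anti-PrC and 1 anti-His ChIP libraries, 33 inputs and 5 whole-genome sequencing libraries. Groups were taken from the labels: 98 of the 101 groups had 1 library, and 3 groups had 2 (Hi-C of the parS -117 strain without xerD, and the XerD-mGFP ChIP with its input). No comparison therefore had a replicate check on both sides, no p-values were computed, and nothing in the labels says whether the paired libraries came from separate cultures.

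The ChIP, input and whole-genome files hold a signal, the sequencing depth at each base as deposited by the authors, over 4033459 bases for B. subtilis and 2821361 for S. aureus. Reads were mapped with Bowtie2 2.1.0, per the submitters' processing notes, and the genome build is not given in the sources used here. Read counts cannot be recovered from such depths, so the counting intervals foreseen in the design could not be computed. The spread of the paired libraries and the 95% range over 1000 resamples of 10 kb blocks were used in their place. The block range covers unevenness along the chromosome only, not differences between cultures. Mean depth was 26.4 to 78.0 (median 38.0) in the anti-SMC libraries, 11.4 to 54.5 in the anti-GFP libraries, 16.8 to 20.8 in the anti-PrC libraries, 34.7 in the anti-His library, 11.6 to 62.2 in the inputs and 8.56 to 14.4 in whole-genome sequencing. The precision this depth gives at single sites was not measured beyond the spread of the paired libraries.

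The Hi-C files hold a fraction, the normalised contact score between 10 kb bins deposited by the authors, made with HindIII digestion per the labels' protocols. Each row of a matrix sums to about 1, and the normalisation method is not given in the sources used here. The number of read pairs behind the scores is unknown. The paired files were not identical: the correlation across bins was 0.812 for the XerD-mGFP ChIP, 0.936 for its inputs and 0.967 for the Hi-C matrices, and bins are not independent replicates.

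Positions of parS sites and arrays are given in degrees in the labels and were converted to bases from coordinate 0 in proportion to the chromosome length. Maxima of SMC signal lay up to about 10 kb from the positions so obtained. The reference table of genes belongs to another assembly, so its coordinates were not used, and only its gene order served to tell the spoIIIE gap from the sftA gap. Deleted loci were located as runs of bases at or under 0.05 of the median depth in libraries with that deletion label. The depth inside was divided by that of the 10 kb flanks in every library.

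Site enrichment was the share of the ChIP library within 250 bp of a site divided by the same share in its input. XDS1 to XDS5 were placed at the summit of the first XerD-mGFP library within 5000 bp of the labels' positions (depth smoothed over 100 bp) and dif at the gap of the dif deletion libraries. Enriched regions were 500 bp bins with ChIP over input, each scaled to its genome-wide median, of at least 3, joined within 1000 bp. SMC enrichment was ChIP over input in 1000 bp bins over its genome-wide median, leaving out bins with input under 0.1 of the mean. The terminus profile set the median from XDS1 to XDS4, and 100 kb windows beyond it, against a 300 kb window of the arm between XDS4 and XDS5. The step at an array set 100 kb past it against 100 kb before it, leaving 10 kb on each side, minus the same value in the parS -94 strain with no array.

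Hi-C scores were divided by the median score at the same separation. For each separation, the pairs spanning parS with 0.2 to 0.8 of the distance on the left were scanned for the maximum of a 3-bin running mean, and the extent was the largest separation reached with at least 2 times the expected score, allowing gaps of 5 bins. The same scan was centred on 35 other positions spaced 10 degrees apart. The step at an array compared the mean maximum over 20 separations after and before the array was reached. Several measures were added after the data were seen: the score along the path followed by the contacts in a reference strain with the same parS, the contacts across an array in 200 kb squares, the share of the 0 min score after xerD induction in 200 kb bands, the central strip in S. aureus, the position of the largest drop of SMC within 80 kb of an array, the SMC signal at the sites over its flanks 1 to 6 kb away, the level past XDS4 above that of the far arm (200000 to 800000), and the ratio of origin to dif depth over that of the parent strain.

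Region calling, the SMC step, the path score and the Hi-C extent were tested on simulated data, and the other measures were not. With the XerD-mGFP libraries as background and 8066 bins, 3 of 20 simulated sites were found at 3-fold, 20 at 6-fold and 20 at 12-fold, with 0 false regions. The 3-fold sites had a median enrichment of 2.79, so sites near the threshold are mostly missed. Simulated SMC steps of 0, -1 and -2 (log2) came back as 0.00, -1.01 and -2.01 over 9 positions. Simulated path shares of 1, 0.7 and 0.5 came back as 1.01, 0.701 and 0.498 on the background of the SMC degradation library. The planned Hi-C extent was exact on independent noise (500, 1000 and 2000 kb), but on that background a simulated level of 3 gave 500 to 3650 kb for a reach of 500 kb, 1000 to 3830 for 1000 and 340 to 3840 for 2000, and a level of 5 gave 80 to 560, 3650 to 3840 and 260 to 3810 kb. Extents can therefore be wrong in both directions, and the path score carries more weight.

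The named regions were fixed before the data were examined: dif, XDS1 to XDS5, the parS and array positions of the labels, the 20 regions with the largest smaller value of the 2 XerD-mGFP libraries, the 10 largest in S. aureus and the 10 largest 1 kb bins of SMC shared by the parS -94 and parS -117 libraries over 50 kb from parS. The alternatives tried were the window, the input, the scaling, thresholds, bin sizes, means for medians, the expected score, running means and leaving out either paired library. The gene-list enrichment planned for an annotated build was not run because no annotation of the files' build was used here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.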

Results

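The libraries measured where the Xer recombinases, the replication terminator protein Rtp and the chromosome-organising complex SMC sit on bacterial chromosomes, and which parts of the chromosome touch each other. XerC and XerD are site-specific recombinases that resolve chromosome dimers at dif, a site in the replication terminus. SMC complexes are loaded at parS, the binding site of ParB, and move outward along both chromosome arms. Most strains carried a single parS at a chosen position, written in degrees from the origin, and some carried an array of XDS copies (the XerD-bound sites named XDS1 to XDS5 in the labels) or of tetO operators. Each group had 1 library unless 2 are named, so no difference below has a replicate check on both sides and no p-value is given.

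The deletions were checked first. Depth over the xerC gap (1650226 to 1651129, 904 bp) was 0.0008 to 0.031 of the flanks in the 7 libraries labelled as lacking xerC and at least 0.744 in the other 62. The rtp gap (1970145 to 1970512, 368 bp) stood at 0.001 and 0.081 in the strain without rtp, and the lowest other library at 0.382. In the strain without spoIIIE and sftA, which encode DNA translocases, the gaps at 1715322 to 1717670 and 2867795 to 2870432 stayed at or below 0.013 and 0.004. The dif gap (1905587 to 1905607) was placed from the whole-genome and anti-SMC libraries of the dif deletion. Their depth over the flanks, 0 and 0.020, was thus low by construction. The 2 anti-GFP libraries of the deletion, not used to place the gap, also had 0, and whole-genome sequencing of the wild type had 1.78. The 3 inputs labelled as the dif deletion went against their label, with 0.516, 0.576 and 0.630, inside the 0.339 to 3.73 of the 29 other inputs. The XDS1 gap (1717707 to 1717726) was placed where the ChIP of the XDS1 deletion was lowest, so the 0 in that library was fixed in advance. The input of the XDS1 deletion had 0.658. At this gap the strains lacking XDS1 to XDS5 had 1.05 in ChIP, 0.593 in the input and 0.406 in whole-genome sequencing. The 3 inputs of the dif deletion therefore do not show the deletion of their label, for a reason that was not tested. The input of the XDS1 deletion does not show it either, but that gap rests on 1 library. Ratios at dif and XDS1 in these strains are therefore also given with no division by input. The short XDS edits were visible only in part. In the strain lacking XDS1 to XDS5 the lowest depth of 20 bases was 0.113 at XDS4, 0.173 at XDS5, 0.244 at XDS3, 0.406 at XDS1 and 0.725 at XDS2, against 0.975, 0.444, 0.65, 0.525 and 0.5 in the wild type.

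The xerD gap (2265606 to 2267330, 1725 bp) went against the labels of 2 inputs. Depth was taken over an inner part of this gap only, because the deletion was narrower in a strain. The input labelled as the parS -94 strain with 12 XDS and no xerD had 1.11 of the flanking depth there, while the input labelled as the tetO120 strain had 0.00. Both ChIP libraries matched their labels, with 0.00 and 1.21. Values from these inputs are given as labelled, with the main ones also after exchange of the 2 inputs. A 12 kb segment close to dif (1934001 to 1946000) also differed between strains. Its depth over the flanks was 4.41 in the input and 2.67 in the ChIP of the 12 XDS strain without xerC, 4.77 in the input labelled tetO120, 2.56 in the ChIP of the 12 XDS strain without xerD, and 2.89 and 2.05 in the input and ChIP of the parS -117 strain without rtp. It was 0 in the strain without spoIIIE and sftA and 0.833 to 1.22 in the other 48 input, anti-SMC and whole-genome libraries.

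**Figure D1:**
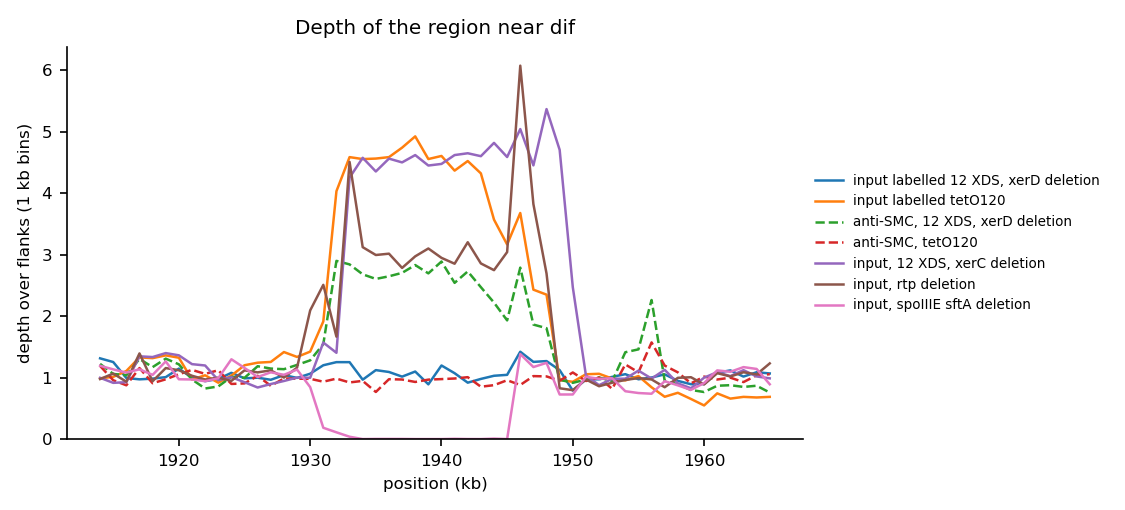
Depth (1 kb bins, divided by the flanks) against position in kb around the segment close to dif, 1 line per library (solid, inputs; dashed, anti-SMC ChIP). The inputs labelled tetO120 and 12 XDS without xerC run above 4, the input without rtp lies near 3 and the input without spoIIIE and sftA falls to 0.

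XerD binding was mapped to ask where the protein sits outside dif. XerD-mGFP was enriched at XDS1 (1717726) by 20.9 and 15.1 times input in the 2 libraries, at XDS3 (1989091) by 8.45 and 8.59, at XDS4 (2033425) by 10.0 and 7.81, at XDS2 (1912641) by 5.69 and 5.01 and at dif (1905597) by 7.03 and 8.01. XDS5 (2597020) was the weakest, at 2.11 and 1.82, close to the upper 2.5% of background positions (1.57 and 1.75). The same sites were enriched with another tag: XerD-PrC gave 21.0 at XDS1, 10.8 at dif, 10.1 at XDS3, 9.52 at XDS2, 8.08 at XDS5 and 6.80 at XDS4. Exactly 5 regions passed 3 in both XerD-mGFP libraries, namely XDS1 to XDS4 and dif. The remaining 15 of the 20 strongest regions had smaller values of 1.59 to 2.14, and 10 of them reached 2 within 1 kb in XerC-PrC and 11 in XerC-mGFP, so most of them were not specific to XerD. The count rested on the second library, since the first alone gave 24 regions.

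This map differed in the libraries without the partner protein or without single sites. Without xerC, XerD-mGFP enrichment was 98.9 at XDS1, 45.7 at XDS3, 37.0 at XDS2, 30.7 at XDS4 and 20.7 at XDS5, a rise of 1.79 to 3.4 (log2) over the mean of the 2 parent libraries, whose own spread was at most 0.33. At dif it fell instead to 2.37, -1.66 on the log2 scale. Deleting dif left 0.656 at dif (0.331 with no division by input) and 8.47, 4.08, 3.58, 4.69 and 1.39 at XDS1 to XDS5, with log2 differences from the parent of -1.07, -0.39, -1.25, -0.91 and -0.50. Deleting XDS1 left 1.11 at XDS1 (log2 -4.00, and 0.724 with no division by input), with 6.22, 4.73, 6.81 and 2.11 at XDS2 to XDS5 and 4.48 at dif. Placing XDS1 at yrdQ gave a region with its summit at 2540250 and an enrichment of 37.8, where the 2 parent libraries had 0.875 and 1.29. In that library the other sites were also higher, at 48.3 for XDS3, 43.4 for XDS4, 41.9 for dif, 27.0 for XDS2 and 5.57 for XDS5. XDS1 had 101, which may include reads of the inserted copy. The input of that strain had 1.77 of the flanking depth at the XDS1 gap, the highest of the inputs without an XDS1 deletion label (median 0.766). A rise at XDS3 and XDS4 as large as that without xerC thus occurred with xerC present. In both libraries other regions rose too (16.4 with XDS1 at yrdQ and 12.6 without xerC near 915750, against 5.77 and 1.79 in the parent libraries). The rise at XDS1, XDS3 and XDS4 can therefore not be told from a difference between single libraries, whereas dif went in opposite directions. XerD(Y277F)-mGFP, which carries a substituted tyrosine, kept 5.37 at dif but had only 1.47, 1.26, 1.65, 1.1 and 1.17 at XDS1 to XDS5. These last values lay within or near its background (upper 2.5% at 1.54), and XDS3 fell below 1 (0.792) with no division by input.

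Of the 6 named sites, XerC was clearly enriched at dif only. XerC-mGFP was enriched 3.59 times at dif and 0.752 to 1.79 at XDS1 to XDS5, against an upper 2.5% of background of 1.77. It had 16 regions over 3, of which 1 was dif and the highest reached 6.68, so dif did not stand out from other regions in that library. XerC-PrC gave 6.94 at dif and 0.451 to 1.04 at the XDS sites, and dif was the highest of its 11 regions. XerC-mGFP at dif was 0.550 in the dif deletion and 0.376 in the xerD deletion, or 0.263 and 0.224 with no division by input. The depth at the dif gap was 0 in the first of these ChIP libraries and 0.419 in the second, the lowest of the 9 anti-GFP libraries that keep dif by label. Rtp-YFP, bound to replication terminators, had its strongest regions at 1737750 (375 times input), 1970750 (270), 1867750 (205), 1989250 (71.8) and 1880250 (30.1). The region at 1989250 covers XDS3, where the enrichment was 75.9, while XDS1, XDS2, XDS4 and dif had 2.25, 2.61, 2.02 and 1.13 against an upper 2.5% of 3.43.

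**Figure D2:**
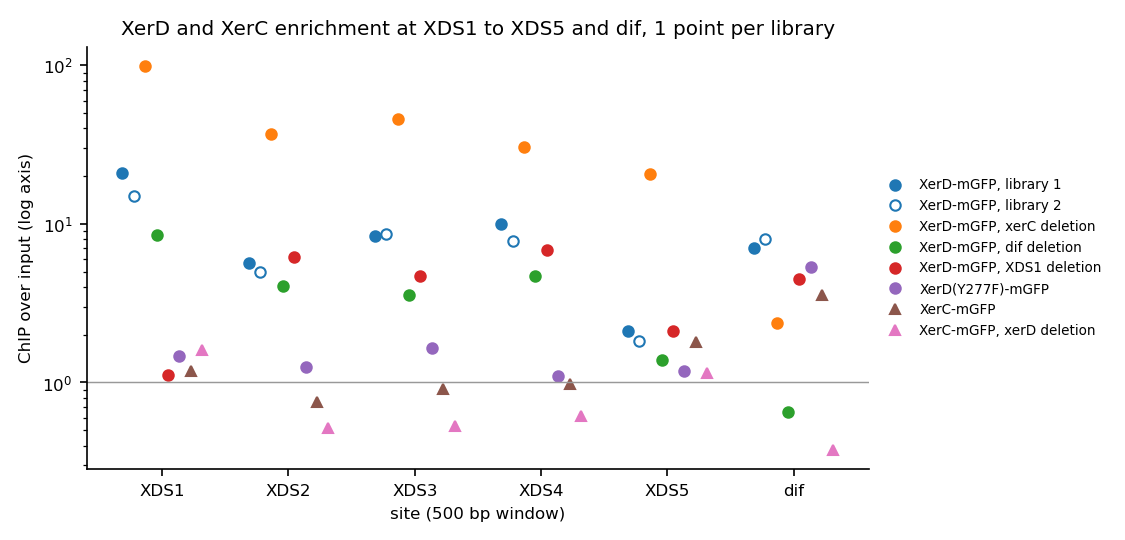
ChIP over input (log axis) in the 500 bp window at XDS1 to XDS5 and dif, 1 point per library; circles are XerD and triangles XerC. XerD without xerC reaches 98.9 at XDS1 and 2.37 at dif, and XerC stands at 3.59 at dif.

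In S. aureus, XerD-His6 was enriched over input by at least 3 in 57 regions, of which 22 reached 5. The strongest were at 1113250 (59.0), 1255750 (56.3), 1320250 (21.6), 1355750 (21.6), 1219250 (15.9) and 1307750 (13.5). The others of the 10 strongest were at 1900250 (10.3), 1864750 (9.94), 1374250 (9.78) and 2243750 (9.38). Thus 7 of these 10 lay between 1113250 and 1374250, in the middle of the chromosome opposite coordinate 0. The genes at these summits are not named because no annotation of this build was used here, and no untagged control was analysed here, so shared background regions cannot be excluded.

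SMC profiles were compared to ask what happens to complexes from parS -117 when they reach the terminus. In the parS -117 strain SMC stood at 4.57 times the genome median on the arm between XDS5 and XDS4 and at 1.2 between XDS4 and XDS1, a log2 ratio of -1.93 (95% block range -2.29 to -1.69). The ratio was similar without rtp (-1.89) and without spoIIIE and sftA (-1.68). It was -0.81 without xerC, -0.61 without dif, -0.31 without XDS1 to XDS5 and -0.05 without xerD (block range -0.24 to 0.14). The log2 differences from the parS -117 strain were therefore 0.04, 0.25, 1.12, 1.32, 1.62 and 1.88. Most of the difference lay in the arm: its level was 2.00 without xerC, 1.79 without dif, 1.38 without XDS1 to XDS5 and 1.39 without xerD, while the level past XDS4 stayed at 1.06 to 1.34 in all 7 strains. These levels are relative to the genome-wide median of each library. The scaling itself holds levels near that median close to each other, so the levels are not amounts of SMC that can be compared between strains.

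Because the arm level differed so much, the level past XDS4 was also expressed as a share of the arm's level, both taken above the far arm. That share was 0.149 in the parS -117 strain, 0.111 without rtp, 0.158 without spoIIIE and sftA, 0.339 without xerC, 0.363 without dif, 0.584 without XDS1 to XDS5 and 0.920 without xerD. In the 100 kb beyond XDS1 it was 0.072, 0.058 and 0.062 in the first 3 strains, 0.108 without xerC, 0.039 without dif, 0.602 without XDS1 to XDS5 and 0.392 without xerD. The ratio of ChIP over input was the most uneven in the XDS1-5 deletion, with an SD of neighbouring 10 kb medians of 0.48 (log2) against 0.20 to 0.33 in the other 6, so its windows are less certain. Its ChIP and input taken alone had 0.31 and 0.35, less than the 0.46 and 0.42 without spoIIIE and sftA. The peak at parS itself was 36.9 in the parS -117 strain, 42.1 without rtp, 26.0 without spoIIIE and sftA, 13.8 without XDS1 to XDS5, 9.90 without dif, 8.33 without xerC and 4.28 without xerD.

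SMC was also concentrated at the XerD sites. In the parS -117 strain the signal over its own flanks was 18.5 at XDS3, 16.8 at XDS2, 13.0 at XDS1, 7.13 at XDS4, 7.11 at dif and 1.48 at XDS5. Without xerD it was 2.53, 0.992, 1.72, 0.911, 1.43 and 1.57 at the same sites, and without XDS1 to XDS5 it was 1.52, 0.781, 1.18, 1.55, 1.61 and 1.36. The 1.61 at dif rests on an input with an unusual 3.73 of the flanking depth at the dif gap. Undivided ChIP depth at that gap was 6.11 over the flanks without XDS1 to XDS5 and 6.59 in the parS -117 strain. A loss of SMC at dif is therefore not shown without XDS1 to XDS5. Without xerC it was 6.91, 6.58, 4.17, 4.69, 2.78 and 1.98, and without dif it was 6.37, 4.92, 3.91, 4.5, 1.65 and 1.65 (1.25 at dif with no division by input). The maximum at parS was lower too, at 4.28 without xerD, 8.33 without xerC and 9.90 without dif, against 36.9 in the parS -117 strain. Lower values at the sites in these libraries can therefore not be told from lower SMC enrichment in the whole library. Away from parS, the strongest 1 kb bin shared by the parS -94 and parS -117 libraries was at XDS4 (2033001, 10.3 and 24.2) and the third at XDS3 (1989001, 7.03 and 22.6). The other 8 of the 10 lay at 2784001, 2914001, 915001, 2785001, 2853001, 2471001, 2149001 and 95001. Of these, the bins at 915001 and 95001 were also raised with Rtp-YFP (14.1 and 6.69) and XerC-PrC (4.91 and 3.96).

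**Figure D3:**
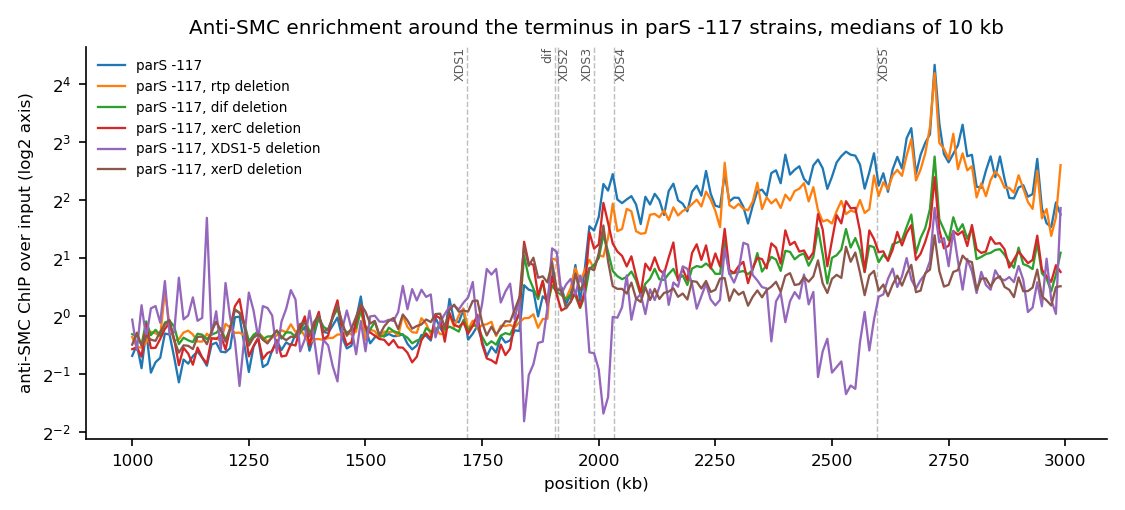
Anti-SMC ChIP over input (log2 axis, medians of 10 kb) against position in kb from the terminus to parS -117, 1 line per strain. On the arm the parS -117 strain and the strain without rtp run highest (medians 4.57 and 3.92), and in the 100 kb left of XDS1 the levels are 0.840 to 1.13.

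Arrays of XDS copies tested whether ectopic sites change SMC past them. In parS -94 strains with the array at -109, the 100 kb past the array had less SMC than the 100 kb before it once 4 or more copies were present: the step minus that of the strain with no array was -1.08 for 4 copies, -1.46 for 12 copies and -1.73 for 12 copies without xerC. With 1 and 2 copies it was -0.12 and -0.01. Without xerD no step down was seen (0.12, and 0.07 with the inputs exchanged), whereas the Y277F strain kept -0.92. A control array of 48 tetO copies bound by TetR-CFP at the same place gave -0.19. With 12 copies on the other side of parS, at -80, the step was -1.76. For parS -59 with 12 copies at -109 no strain without the array was analysed here, and the raw step was -1.07. Block ranges of the raw steps were -1.47 to -0.82 for 4 copies, -1.88 to -1.02 for 12, -0.10 to 0.13 without xerD (-0.13 to 0.11 with the inputs exchanged) and -0.39 to -0.14 for tetO48.

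The signal at parS differed between these libraries, which limits the smallest steps. The maximum near parS -94 was 71.5 with no array, 417 with 4 copies, 357 with 12 copies and 402 without xerC, but 34.2 with 1 copy, 16.9 with 2 copies and 33.9 without xerD (30.3 with the inputs exchanged). SMC in the window before the array was 7.22 with 4 copies, 4.99 with 12, 7.5 with 12 without xerC, 4.48 with Y277F and 4.86 with tetO48. It was only 1.56 and 1.26 with 1 and 2 copies and 1.86 without xerD (1.83 with the inputs exchanged), so a lost step in these 3 strains cannot be told from a lack of SMC to be lowered. The highest 1 kb bin near the array had 24.8 with 4 copies, 22.1 with 12, 47.6 without xerC, 64.9 at -80 and 17.9 with Y277F. It had 7.87 with tetO48, 5.39 without xerD (4.74 with the inputs exchanged), 2.90 with 1 copy and 2.00 with 2 copies. Such a bin is always found, and its value was not computed with no array. With similar SMC before the array (4.99 and 4.86), 12 copies had more than tetO48. The low values without xerD and with 1 and 2 copies cannot be told from the lower SMC before the array. With 120 tetO copies at -122 bound by the membrane-anchored Tsr-TetR-YFP the step was -1.17, but -0.63 with the inputs exchanged, -0.33 with means and 0.05 in 50 kb windows. Its maximum near parS was 89.6 (78.9 with the inputs exchanged) and that at the array 3.99 (4.46). The largest drop in that strain lay at 2618564 (-1.40), -48 kb from the position of the label, and with the inputs exchanged at 2614564 (-0.91).

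**Figure D4:**
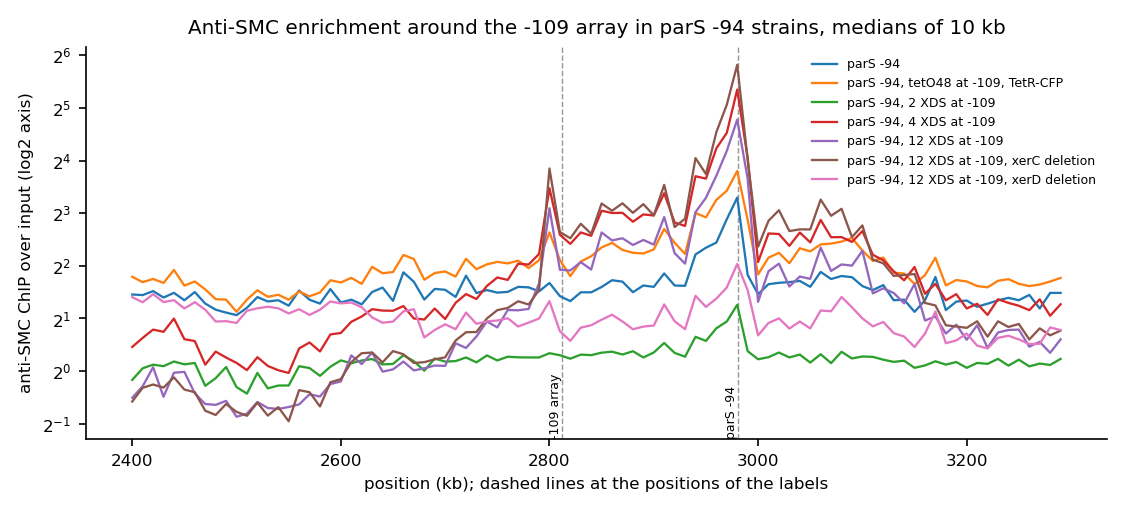
Anti-SMC ChIP over input (log2 axis, medians of 10 kb) against position in kb around parS -94 and the -109 array, 1 line per strain. Past the array, to its left, the strains with 4 and 12 XDS copies fall (steps -1.08 and -1.46), while those with tetO48 and without xerD do not (-0.19 and 0.12, inputs as labelled).

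Hi-C asked how far the arms on both sides of an added parS were brought together. From parS +58, +91, +117 and +153 the contacts extended over 2390, 1870, 1280 and 430 kb. With other thresholds the extents were 70, 2910, 2390 and 540 kb at 1.5 and 0, 0, 940 and 0 kb at 3. The shortening toward the terminus was thus kept from +91 to +153 at 1.5, but not from +58, and not at 3. The mean maximum of the scan, which uses no threshold, was 4.64, 3.06, 2.06 and 1.32 at 1000 to 1500 kb. It fell in the same order at 1500 to 2000 kb, from 3.78 to 1.34. That order was not kept at 0 to 500, 500 to 1000 or 3500 to 4000 kb. A maximum is always returned, and it was 2.13 at 1000 to 1400 kb in the parS -94 library with SMC degradation. From +58, +91, +117 and +153 the terminus-side ends lay at 1910, 1980, 1980 and 2000 kb, in the stretch that holds XDS2 and XDS3. From parS -117 the extent was 2780 kb and the terminus-side end 1980 kb. In the 2 libraries without xerD the extents were 1890 and 1930 kb, with terminus-side ends at 1730 and 1590 kb. These ends belong to different separations. At matched separations of 1850 to 2350 kb the median end was 1790 kb with xerD and 1570 and 1580 kb without it, so all 3 lay beyond dif. The scan always returns an end, however. Its mean score there was 2.05 with xerD and 1.91 and 1.89 without it, below the 2.51 of the parS -94 library with SMC degradation. These ends therefore do not show contacts past dif. Along the path of the parS -117 strain the mean score was 2.20 with xerD against 2.04 and 2.07 without it at 200 to 400 kb, and 3.70 against 2.84 and 2.86 at 800 to 1000 kb, the band with the widest gap. This path favours the strain with xerD. Along the path of the first library without xerD the same band had 3.49 against 2.95 and 2.89. The strain with xerD had 1 library, so a spread of the path score is known only without xerD (SD 0.030 on the log2 scale, over 5 bands). Each of these extents changed by over 1.5 times with a threshold of either 1.5 or 3, and on a real background the simulated extents were wrong in both directions.

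XDS arrays lowered the contacts between the arms. In parS -94 strains the mean score along the path at 300 to 1500 kb was 3.32 with tetO48 at -109, 2.16 with 4 XDS copies, 1.29 with 12 copies and 1.23 with 12 copies without xerC. It was 2.75 with 12 copies but no xerD and 2.03 with Y277F. With 12 copies at -80 it was 1.71. After degradation of SMC it was 1.12 in another strain with the same parS and array, of which no untreated library was analysed here, and no degradation library of a strain with the -109 array was analysed here. With tetO120 at -122 it was 2.51. The path was that of the tetO48 strain, but along the path of the strain without xerD each score differed by less than the spread used (3.28 with tetO48, 2.78 without xerD, 1.29 with 12 copies). The extents at the planned threshold were 2180 kb with tetO48, 2060 with tetO120 and 1980 with no xerD, against 660 with the array at -80, 430 with 4 copies, 390 with Y277F, 300 with 12 copies and 280 without xerC. At a threshold of 1.5 only the last 2 stayed short (360 and 350 kb), while 4 copies, Y277F and the array at -80 reached 3370, 2860 and 3370 kb. In the simulation a reach of 2000 kb also came back as 260 or 340 kb, so the extents are given for completeness only. No parS -94 Hi-C library without an array was analysed here, so tetO48 served as the reference.

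The planned step at the array compared the scores just after and just before the array was reached. It was 0.86 (log2) with tetO48, 0.68 with no xerD, 0.51 with 4 copies, 0.43 with Y277F, 0.26 with 12 copies and 0.10 with 12 copies without xerC. All were above 0 for a reason that was not tested, and the step at -109 was not computed in a strain without an array there. For tetO120 it was 0.24, against 0.01 at the same place in the tetO48 strain, and for the -80 array -0.18, against -0.04. For parS -59 with the -109 array it was -0.27. For parS -1 it was -0.27 at +26, against -0.06 without an array there, and -0.06 at -19, against 0.50 without an array there.

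Contacts across the array were measured as well, as the lowest value among neighbouring 10 kb bins around the position of the label. The 101 positions used for comparison were treated alike. Contacts between the 200 kb on either side of the -80 array were 0.625 of the expected score with parS -94 (2 of 101 positions were as low). With no added parS they were 0.764 (6 of 101). After SMC degradation, in other strains with the same sites, they were 0.922 and 0.932. Other parS -94 strains, which had no array at -80, gave 0.754 with tetO48 and 0.788 without xerD, so part of the dip at this place was present without XDS copies. At -109 they were 0.792 with 12 copies (9 of 101) and 0.839 without xerC (9 of 101), but 0.941 with 4 copies (33 of 101) and 0.959 with Y277F (40 of 101), against 1.08 without xerD and 1.05 with tetO48. For parS -59 they were 0.645 (5 of 101).

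**Figure D5:**
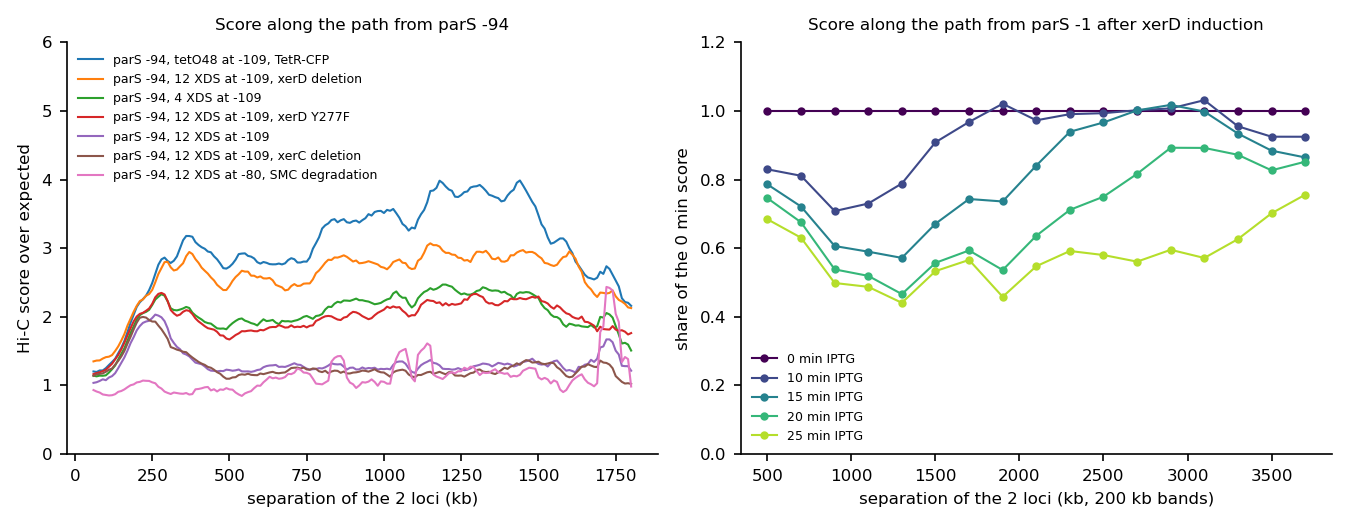
Left, Hi-C score over expected along the path from parS -94 against the separation of the 2 loci in kb, 1 line per strain; right, score from parS -1 as a share of the 0 min score in 200 kb bands, 1 line per time after IPTG. With 12 XDS copies the mean score is 1.29 against 3.32 with tetO48, and the lowest shares at 10, 15, 20 and 25 min are 0.708, 0.572, 0.466 and 0.441.

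The timing was followed in a parS -1 strain with 12 XDS copies at both +26 and -19, no native xerD and xerD under an IPTG promoter (1 mM IPTG). The loss was first seen at middle separations and then reached longer ones. At 10 min the score had dropped below 0.8 of its 0 min value in 3 of 17 bands, from 800 to 1400 kb, with 0.830 and 0.811 at 400 to 600 and 600 to 800 kb. It was below 0.8 at 15 min in 8 bands up to 2000 kb, at 20 min in 11 bands up to 2600 kb and at 25 min in 17 bands up to 3800 kb. The lowest share was 0.708 at 10 min (800 to 1000 kb), and 0.572, 0.466 and 0.441 at 15, 20 and 25 min (1200 to 1400 kb). The extent was 3460 kb at 0 min, then 3340, 980, 860 and 770 kb, but at a threshold of 3 it was 340 kb at 0 min and 380 kb at each later time. The step at the +26 array moved from 0.04 to -0.07, -0.19, -0.27 and -0.31, and that at the -19 array from 0.39 to 0.21, 0.12, 0.08 and 0.08. In the strain with native xerD and both arrays they were -0.24 and 0.07, and the extent was 1020 kb. With 10 separations the step changed sign at +26 at 10 min and at -19 at 15, 20 and 25 min, so the steps are less certain than the bands. The bands in turn follow the path of the 0 min library, which favours that library. Along the path of the 25 min library the lowest share was 0.803 at 10 min, so no band fell below 0.8, and the outermost band below it ended at 1800, 2200 and 3200 kb at 15, 20 and 25 min. The first band (400 to 600 kb) stayed at 1.16 to 1.21, so any loss in that band was seen on 1 of the 2 paths only.

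Strains with no added parS by label were compared over the same path from the origin. Whether those with the -80 array kept the native parS sites was not checked. At 800 to 1200 kb the score was 2.27 without dif, 2.16 without XDS1 to XDS5 and 1.90 without xerD, and at 2800 to 3200 kb it was 1.74, 1.69 and 1.60. A wild type Hi-C library was not analysed here, so these values have no reference. With 12 XDS copies at -80 and no added parS the score was 1.59 at 1200 to 1600 kb and 0.708 at 2400 to 2800 kb, against 1.2 and 1.05 after SMC degradation in another strain. At 200 to 400 kb it was 0.703 with that array, against 1.34 without dif, 1.31 without XDS1 to XDS5 and 1.31 without xerD.

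In S. aureus the arms touched along a strip centred on the origin. The central score over expected in the wild type was 1.52 at 100 to 300 kb, 1.59 at 300 to 600, 1.69 at 600 to 900, 1.61 at 900 to 1300 and 1.57 at 1300 to 1800 kb, with at most 1 of 35 control centres as high. At 1800 to 2300 kb it was 1.37, with 3 of 35 as high. Without parB, which encodes the parS-binding protein, the same bands had 1.03, 1.07, 1.18, 1.13 and 1.1, with 18, 9, 0, 1 and 7 of 35 control centres as high. The strip was thus lower than in the wild type but still above nearly all controls at 600 to 1300 kb. With 12 XDS copies inserted at geh (+40) they had 1.55, 1.82 and 1.55 up to 900 kb and then 1.18 and 1.13, with 0, 0, 2, 4 and 10 of 35 control centres as high. The planned extent did not separate these strains: it was 310 kb in the wild type and without parB and 2620 kb with the array, and 14, 27 and 3 of the 35 control centres gave as long a reading. The step at the array was 0.14, against 0.27 in the wild type and 0.48 without parB.

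Whole-genome sequencing asked whether the deletions change replication along the chromosome. Depth at the origin over that at dif was 2.70 in the wild type (95% block range 2.59 to 2.83), 2.71 without dif, 2.66 without xerD, 2.64 without XDS1 to XDS5 and 2.38 without xerC (2.27 to 2.48). In the 50 kb windows used here, only the xerC value lay outside the wild type range. The value without xerD was lower in wider windows, as given further below. Each deletion was also set against its own parent, a comparison added after the data were seen. Without xerC the ratio was lower in all 4 comparisons, with log2 differences of -0.18 in whole-genome sequencing and -0.12 (parS -117), -0.13 (12 XDS at -109) and -0.04 (XerD-mGFP) in the inputs. The block ranges were apart in 2 of the 4, and the last difference was smaller than the 0.08 between the 2 parent inputs. That last difference changed sign with means in place of medians. Without xerD the differences were -0.02 in whole-genome sequencing and -0.38 (parS -117), -0.20 (XerC-mGFP) and -0.02 (12 XDS, -0.58 with the inputs exchanged) in the inputs. Without dif they went both ways (-0.01 to 0.16). Both arms sloped less than in the parent in all 4 comparisons without xerC, and also in all 4 without dif. Without xerD the ratio was lower in all 5 comparisons, and each arm sloped less in 4 of the 5. The 12 XDS strain was counted here both as labelled and exchanged. Its input as labelled kept depth at the xerD gap (1.11 of the flanks), so it may not stand for that deletion. The block ranges were apart in 1 of the 5, that with the inputs exchanged. With medians, the lower ratio without xerC was thus repeated in direction. The ratio without xerD was also lower, but by only -0.02 in whole-genome sequencing. Each comparison had 1 deletion library, and the cause was not tested. The slopes of the right arm were -0.72 per Mb (log2) in the wild type and without dif, -0.70 without XDS1 to XDS5, -0.63 without xerD and -0.61 without xerC.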

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

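All tests in this part were chosen only after the results were seen. The 12 kb segment close to dif (1934001 to 1946000) stood above its flanks in libraries whose depth outside the sites and windows was not otherwise compared. Its depth was 4.77 in the input labelled tetO120, 4.41 in the input and 2.67 in the anti-SMC library of the 12 XDS strain without xerC, 2.56 in the anti-SMC library of the 12 XDS strain without xerD, and 2.89 and 2.05 in the input and anti-SMC library of the parS -117 strain without rtp, against at most 1.22 in 48 other libraries.

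Enrichment during ChIP is argued against in the strain without rtp and in the 12 XDS strain without xerC. Their inputs had 2.89 and 4.41, more than their ChIP libraries (2.05 and 2.67). In the 12 XDS strain without xerD, the input as labelled had 1.00 and the ChIP 2.56. Enrichment during ChIP stays open for that strain unless its true input is the one labelled tetO120 (4.77). Placement of reads from repeats is argued against by the wild type, where the segment stood at 1.00. The xerC or xerD deletion alone is argued against by 8 other libraries of strains without these genes, the lowest at 0.857. A candidate explanation is a gain of copies of this segment in those strains, as a difference between cultures or strain lineages that was not tested. The Hi-C libraries of the 2 strains with 12 XDS hold normalised scores with rows that sum to about 1, so they were not used to read copy number, and the strain without rtp had no library outside its ChIP and input.

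The xerD gap went against the labels of 2 inputs, and the segment close to dif offers a second mark of strain identity. In the input labelled tetO120 it stood at 4.77, as it was raised (2.56) in the ChIP of the 12 XDS strain without xerD, and it stood at 1.00 in the input carrying that strain's label. A mixture of both samples is argued against because the xerD gap was at 1.11 in that input and at 0.00 in the other, with nothing between. An exchange of the 2 inputs is therefore a likely explanation, as a hypothesis, and the steps and maxima of these strains are given both ways.

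In the parS -117 strain without xerD, SMC past XDS4 was close to the level of the arm. A lower overall enrichment in that library was not excluded, as its maximum at parS was 4.28 against 36.9 in the parS -117 strain. The share kept past XDS4 was 0.920 against 0.149. Shrinking both levels above the far arm alike would not change that share. But the level past XDS4 hardly differed, so the share rises with any fall of the arm and cannot decide this. The level past XDS4 itself differed from that of the parS -117 strain by only 0.16 (log2), while the arm was lower by 1.72. The pattern may thus come from a lower arm level alone, and fewer complexes arriving from parS would be a possible reason. But both levels are relative to the genome-wide median of each library. A difference in that median would shift both, so these values do not give amounts of SMC. The strain without XDS1 to XDS5, which keeps xerD, differed from the parS -117 strain by 1.62, which is consistent with a loss of XerD function at these sites, but its arm was lower too and its ratio of ChIP over input was the most uneven. All of these explanations stay open in the ChIP data, and the deletion strains have 1 library each.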

How the results depend on the processing

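The alternatives for the Hi-C path score and its path, the induction bands, the S. aureus strip, the contacts across arrays, the largest drop, the exchanged inputs, the ratio of origin to dif over the parent and the input of the XDS1-5 deletion library were chosen after seeing the data, as were these measures. The others were fixed before the data were examined. Of 545 alternatives over 211 results, 235 moved a value by less than the spread used, 303 moved it further and 7 reversed the sign of a value larger than its spread. Sign changes of smaller values, such as that without rtp below, are not among the 7. Where a value changed, the cause was not tested, except that fewer libraries, wider windows or stricter thresholds change what is counted by construction. The order of the 6 deletion strains in the SMC terminus profile held under the 3 alternatives fixed beforehand, but with means the difference without rtp was -0.09, so that strain and the parS -117 strain changed places. The SMC steps for 4 or 12 XDS copies with xerD present stayed below 0 under every alternative run. What depth limits was not measured, since the simulation did not vary it, and the simulated 3-fold sites were mostly missed with a median enrichment (2.79) under the threshold. No paired analysis was possible because the result of each comparison comes from no test. The XerD-mGFP ChIP libraries and their inputs share 2 replicate numbers, and each ChIP library was divided by the input of the same number. The gene-list enrichment was not run.

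XerD-mGFP enrichment at XDS1 and dif moved from 17.8 and 7.5 (geometric means) to 8.55 and 4.31 with a half-window of 500 bp and to 9.34 and 3.31 with no division by input, and ranged from 15.1 to 20.9 and from 7.03 to 8.01 when either library was left out. At dif it moved to 0.854 (500 bp) and 0.331 (no input) in the dif deletion, and to 1.77, 1.34 and 2.86 (median scaling) in the xerC deletion. XDS1 in the XDS1 deletion moved to 0.724 with no input. XerC-mGFP at dif moved to 2.04 with 500 bp, 2.11 with no input and 4.28 with median scaling. XerD(Y277F)-mGFP at XDS3 reversed to 0.792 with no input. Over all sites, 500 bp moved 45 values down and 7 up, no input 62 down and 0 up, and median scaling 1 down and 31 up. Of the 225 alternatives for single sites or places, 160 moved. The XerD region count ranged from 5 to 24 when either library was left out, 24 being that of the first alone. The S. aureus count was 22 with a threshold of 5 and 26 with 1 kb bins.

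With means of 1 kb bins the terminus difference was 1.5 without xerD and 1.12 without XDS1 to XDS5, and the tetO120 step was -0.33. In 50 kb windows the steps were -0.59 for 4 copies, -0.81 for 12, -0.57 for Y277F, -0.76 for parS -59, and 0.051 for tetO120, a reversal. With the input of the parS -117 strain, the difference without XDS1 to XDS5 was 1.91, above the 1.88 without xerD. The xerD deletion's ratio of origin to dif was 2.5 in 100 kb windows. With means of 1 kb bins the log2 ratio over the parent was -0.79 for 12 XDS without xerC and -1.47 for 12 XDS without xerD with the inputs exchanged, and 0.05 for XerD-mGFP without xerC, where the sign changed. The window of 50 kb on each side of dif holds the segment close to dif, at 4.41 and 4.77 of its flanks in the 12 XDS inputs used here. With that segment left out, the ratios of origin to dif were 2.45 without xerC and 1.84 without xerD, against 2.64 in the parent.

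All 23 B. subtilis Hi-C extents tried moved with both other thresholds, and that after SMC degradation was not tried. In the order parS +58, +91, +117, +153, -117 and -117 without xerD, they were 70, 2910, 2390, 540, 3840 and 3815 kb at 1.5 and 0, 0, 940, 0, 1190 and 0 kb at 3. For the parS -94 strains with 4 copies, 12 copies, 12 without xerC, 12 without xerD, Y277F, 12 at -80, tetO48 and tetO120 they were 3370, 360, 350, 3500, 2860, 3370, 3830 and 3820 kb at 1.5 and 0, 0, 0, 370, 0, 0, 420 and 690 kb at 3. For parS -59, and for parS -1 with arrays at +26, at -19 and at both, they were 3810, 3050, 2860 and 3070 kb at 1.5 and 1070, 730, 360 and 370 kb at 3. With the mean score per separation they were 2180 for +58, 1890 for -117, 820 for -117 without xerD, 1920 for 12 copies without xerD, 2000 for tetO48, 1520 for parS -59, and 1130, 540 and 980 for parS -1 with +26, -19 and both. With a running mean of 5 bins they were 1810 for +91, 1790 for -117, 155 for -117 without xerD, 0 for 12 copies, 0 for 12 without xerC, 510 for -80, 2030 for tetO48 and 1030 for parS -1 with -19. At 0, 10, 15, 20 and 25 min after induction they were 3840, 3760, 3610, 3560 and 3310 kb at 1.5, 340, 380, 380, 380 and 380 kb at 3, and 3050, 3190, 830, 660 and 700 kb with the mean score per separation. With a running mean of 5 bins they were 3330, 780 and 700 kb at 0, 20 and 25 min. Leaving out either library without xerD gave 1890 to 1930 kb. In S. aureus the extent was 2630 kb in the wild type and 340 kb without parB at 1.5, and 340 kb with the array when the mean was the expected score.

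With 10 separations the steps for 4 copies, 12 copies, 12 without xerC, 12 without xerD, Y277F, 12 at -80, tetO48 and tetO120 were 0.31, 0.22, 0.037, 0.42, 0.28, -0.12, 0.53 and 0.017, and -0.061, -0.12 and -0.27 for parS -59, parS -1 with +26 and parS -1 with -19. With the mean score per separation they were 0.14, 0.64 and 0.80 for 12 without xerC, 12 without xerD and tetO48. After induction, with 10 separations, the +26 step was 0.027 at 10 min (reversed), -0.035 at 15, -0.043 at 20 and -0.11 at 25 min, and the -19 step 0.20 at 0 min, 0.0019 at 10 min, and -0.082, -0.12 and -0.11 at 15, 20 and 25 min (reversed). In the strain with native xerD they were -0.20 and -0.18, the second reversed. With the mean score per separation the path scores were 3.00 for tetO48, 2.57 without xerD, 2.38 for tetO120, 2.08 for 4 copies, 1.98 for Y277F and 1.05 after SMC degradation. Along the path of the strain without xerD the mean score at 200 to 1200 kb was 3.06 in the parS -117 strain, against 3.14 along its own path. The outermost band with a lost score ended at 1600, 2200 and 3400 kb at 15, 20 and 25 min with a share of 0.7, and at 3800 and 3800 kb at 15 and 20 min with a share of 0.9. No band was lost at 10 min with a share of 0.7 or along the path of the 25 min library (0 kb), and along that path it ended at 1800, 2200 and 3200 kb at 15, 20 and 25 min. In the S. aureus strip at 300 to 600 and 900 to 1300 kb, the mean score per separation gave 1.48 and 1.48 in the wild type, 1.03 and 1.05 without parB and 1.65 and 1.05 with the array.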

Other observations

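The tests in this part were chosen only after the results were seen. The XerD-mGFP library with XDS1 at yrdQ, like the library without xerC, showed raised signal at regions outside the XerD sites, including 909501 to 916500 (16.4), 160501 to 176500 (13.4), 90501 to 101500 (12.9) and 598001 to 604000 (12.9). The library without xerC had 12.6, 10.4, 7.75 and 9.54 in the highest of the 3 bins of 500 bp around those maxima, while the first XerD-mGFP library had 5.77, 3.77, 3.95 and 5.18 and the second 1.79, 1.31, 1.18 and 1.29. Regions overlapping these were among the strongest of Rtp-YFP, with 16.6 at 915250, 7.36 at 161750, 7.62 at 92750 and 8.85 at 598250. Background of this kind differed between libraries of the same tagged protein, so a fold between libraries was read at the XerD sites only.

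At XDS5 the tags differed more than at any other site. XerD-PrC had 8.08 there, XerD-mGFP 2.11 and 1.82, and XerD-mGFP without xerC 20.7, the largest gain among the sites (log2 3.4). SMC in the parS -117 strain had 1.48 over its flanks at XDS5.

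In the SMC libraries of parS -94 strains, the XDS sites in the terminus lie beyond the -109 array. With 4 copies in the array the signal over its flanks was 16.0 at XDS1, 15.0 at XDS2 and 15.4 at XDS3, with 12 copies 6.19, 2.71 and 3.25, with 12 copies and no xerD 1.07, 1.1 and 1.25 (1.24, 1.03 and 1.61 with the inputs exchanged), with 1 copy 1.99, 2.20 and 2.57, with 2 copies 1.11, 1.32 and 2.06, and with no array 5.30, 6.0 and 9.41. With the array on the other side of parS, at -80, the values were 8.49, 6.92 and 6.68. They were 10.2, 3.09 and 6.18 with 12 copies without xerC, 2.47, 0.916 and 1.3 with Y277F, and 6.04, 9.42 and 8.78 with tetO48. With tetO120 they were 3.78, 3.37 and 4.61 (3.25, 3.63 and 3.58 with the inputs exchanged). The values did not follow the number of copies.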
